A study of Mus musculus with 11 samples.

How the data were processed

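RNA was measured in quadriceps muscle of aged mice, as total RNA isolated with the Direct-zol kit and sequenced by the DNBseq technology per the labels' protocols. The authors deposited 1 table of raw read counts per Ensembl gene, with a column for each of the 11 libraries, made with STAR 2.5.2b and HTSeq 0.6.0 on build GRCm38 per the submitters' processing notes. The strand setting of the counting, the annotation release and the filters on reads are not given in the sources used here, nor are the dose of myriocin and the sex of the mice. The strain is written C57L/6JRj in the labels. Without a stated strand setting, it is not known whether reads of a gene and of an antisense partner were told apart. The spans of 53.9% of the tested genes, introns included, overlap that of another annotated gene on either strand. How many of them share exons was not counted, so the share of genes with uncertain counts is not known.

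The table had 53470 lines, of which 5 were HTSeq summary lines. They held 24.8% to 28.2% of the reads of a library, mainly reads with several alignments (15.2% to 18.1%) and ambiguous reads (6.46% to 7.73%), and stayed out of library sizes and tests. Of 53465 genes, 53360 were matched by identifier to the GENCODE mouse release M21 annotation of GRCm38, which gave symbols and coordinates, and 24179 had 0 counts in all libraries. Gene totals ran from 22241131 to 23163721 reads per library, so that 3 counts, taken as the floor, correspond to 0.130 to 0.135 CPM. Intervals and floors cover counting error and the spread between libraries as fitted, and molecular identifiers are not given in the sources used here, so reads may include PCR copies. Each column was assigned to a sample by its name, and 0 columns were left unassigned. No pair of libraries in a group was a copy of another: the chi-square per degree of freedom between pairs lay between 8.18 and 44.2.

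Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter was filterByExpr by group (minimum count 10, minimum total 15), the scaling was TMM, and the test was the quasi-likelihood F test with robust dispersion (glmQLFit with robust estimation in the current form, glmQLFTest), with treatment as the single factor. P-values were adjusted by Benjamini-Hochberg over the 14117 genes tested, with a threshold of 0.05. Log2 fold changes are myriocin minus DMSO, and CPM values are edgeR's counts scaled to library totals after TMM. SE, the standard error of the log2 fold change, was calculated back from the F statistic. It is the absolute log2 fold change divided by the square root of F. The 95% intervals come from this SE and the fitted degrees of freedom. The levels per library of Alb and S100a8 in the report, and those under the other observations, are CPM without TMM scaling.

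Gene lists for pathways and cell types, together with the named gene rule, the tests and the alternatives, were fixed before the data were examined. Of these lists 38 had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 on log2 CPM with a prior count of 2, 2-sided, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, cameraPR on the signed quasi-likelihood statistics, and an exact permutation test of the mean log2 CPM of a list over all 462 assignments of the libraries to groups of these sizes, for which the smallest possible p is 0.00216. Counts of members past the threshold are given over all genes and adjusted over the list alone. A second set of lists, for liver transcripts, peroxisomal oxidation and the phases of the clock, was added after seeing the data.

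The named genes were the subunits of serine palmitoyltransferase, the 5 genes with the smallest p in each direction (symbol other than a predicted gene, mean of at least 1 CPM), as fewer than 5 genes passed, the 3 members with the smallest p in each list called by camera, and the 2 with the smallest p in other lists that are described. Which of the other lists are described with members was chosen after the values of lists and genes, including which genes turned sign under alternatives, had been seen. Of the genes this rule takes, 3 are not reported here and were not replaced. Alb and the genes named in the closing section as library values were chosen after their values were seen.

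The alternatives planned for the counts of genes and of lists were DESeq2 1.42.0 size factors, upper-quartile scaling, no scaling, no filter except genes without counts, a filter of 10 counts in at least 9 libraries, leaving out mitochondrial genes and the 20 most abundant genes, leaving out each library in turn, replicate number as a block over 10 libraries, and 1 surrogate variable (sva 3.50.0). For genes they further included DESeq2, limma-voom with and without sample weights, edgeR without robust estimation and in its older form, a threshold of 0.10 and a test against a log2 fold change of 0.25. For lists they further included the other set tests and a prior count of 0.5.

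The gene and list tests were tested on simulated data with the means, library sizes and dispersions of these libraries. With no gene changed, 0 genes and 0 lists were called. Simulated genes vary independently of each other, which real genes do not, so the simulation does not cover correlation within lists. Random splits of the real libraries into 5 and 6 (100, the real one included, of 462) serve for that.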

Results

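Gene expression was measured by RNA sequencing in the quadriceps, a large muscle of the thigh, of aged mice given either myriocin or the solvent DMSO. Myriocin is a fungal compound that blocks serine palmitoyltransferase, the enzyme of the first step of de novo sphingolipid synthesis, which leads to ceramides. Treatment began at 18 months of age and lasted 10 weeks. There were 5 DMSO libraries and 6 myriocin libraries. The comparison asks how muscle transcripts of aged mice differ after this treatment. Each library held between 22241131 and 23163721 reads counted in genes, and between 21125 and 21899 genes had at least 1 count. The mean depth was 22747805 ± 327144 reads (SD, n = 5) with DMSO and 22924815 ± 149563 reads (SD, n = 6) with myriocin. Mitochondrially encoded genes took 7.42% to 11.2% of the gene counts and the 20 most abundant genes 33.2% to 37.4%. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between these samples.

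The transcripts of the enzyme that myriocin inhibits had like levels in both groups. Sptlc1 (ENSMUSG00000021468, GRCm38 chromosome 13, 53332748 to 53377397, minus strand), a subunit of serine palmitoyltransferase, stood at 15.7 ± 1.68 CPM (read counts scaled to an equal library total; SD, n = 5) with DMSO and 15.8 ± 0.863 CPM (SD, n = 6) with myriocin. Its log2 fold change, myriocin minus DMSO, was 0.01 with a 95% interval from -0.16 to 0.17. Sptlc2 (ENSMUSG00000021036, chromosome 12, 87305058 to 87388355, minus strand), the partner subunit, stood at 7.19 ± 1.95 CPM (SD, n = 5) with DMSO and 7.26 ± 0.490 CPM (SD, n = 6) with myriocin, and its interval ran from -0.31 to 0.33. The sign of both values changed with the libraries or scaling used. Sptlc3 (ENSMUSG00000039092, chromosome 2, 139493913 to 139637674, plus strand), an alternative subunit, had 0 counts in each of the 11 libraries, which allows up to 0.135 CPM per library (3 counts).

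The wider sphingolipid pathway did not move as a group. Of 13 tested genes of de novo sphingolipid synthesis, 8 had positive and 5 negative log2 fold changes, with a median of 0.01, and 0 passed the test over all genes or adjusted over the list alone. The smallest p-values belonged to Kdsr, the reductase that follows serine palmitoyltransferase (log2 fold change -0.19, SE 0.09), and Cers1, the ceramide synthase most abundant in skeletal muscle (0.24, SE 0.12); edgeR's adjusted p was 0.936 for both. The list gave an adjusted camera p of 0.913. Among 34 tested genes of sphingolipid turnover and conversion, 16 were positive and 18 negative, and 0 passed either adjustment. Its members with the smallest p were Col4a3bp, the ceramide transfer protein (0.19, SE 0.07), and Spns2, a transporter of sphingosine phosphate (0.23, SE 0.10), and the list's adjusted camera p was 0.831.

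No single gene separated the groups in the test over all genes. Of 14117 genes tested with edgeR's quasi-likelihood test, 0 rose and 0 fell at an adjusted p under 0.05, and the smallest adjusted p was 0.513. At an unadjusted p under 0.05 there were 660 genes, 329 of them higher and 331 lower with myriocin, where chance alone gives 706. The counts at the adjusted threshold were 3 with DESeq2, 0 with limma-voom, 0 with limma-voom and sample weights, and 1 with a surrogate variable added to edgeR. The 3 genes of DESeq2 were Sh3rf2, Tirap and Xlr3b. Without Myriocin replicate 4 the number at an unadjusted p under 0.05 was 1449, with 0 past the adjusted threshold. The median log2 fold change over all genes was -0.01, and 33 genes had an absolute value above 1. The 95% interval lay within 1 log2 unit of 0 for 93.3% of the genes, and its median half-width was 0.25. Simulated counts with the dispersion of these libraries held genes changed by several sizes at once, 48 of them 3-fold. There the same test called 93.8% of 48 genes changed 2-fold and 42% of 50 changed 1.5-fold. It called 6% of 50 with the smallest simulated change, and 4 unchanged genes. Many changed genes together ease the adjusted threshold. These shares therefore do not give the chance of calling a changed gene in the real comparison, where 0 genes passed.

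The genes with the smallest p-values are given with their values, none having passed edgeR's adjusted threshold. Sh3rf2 (ENSMUSG00000057719, chromosome 18), an E3 ubiquitin ligase with SH3 domains, stood at 25.1 ± 2.99 CPM (SD, n = 5) with DMSO and 37.5 ± 4.74 CPM (SD, n = 6) with myriocin, a log2 fold change of 0.58 (SE 0.10; adjusted p = 0.513), each of the 6 myriocin libraries lying above each DMSO library. DESeq2 gave it an adjusted p of 0.00184 and the surrogate variable fit of edgeR 0.0236, while over all alternatives it ranged from 0.00184 to 1. Tirap, an adaptor of Toll-like receptor signalling, went from 12.8 ± 1.33 to 16.9 ± 1.02 CPM (log2 fold change 0.41, SE 0.08), with an adjusted p of 0.619 in edgeR and 0.0374 in DESeq2. Xlr3b, a gene of a family of near-identical copies on chromosome X whose reads cannot be assigned with certainty, went from 3.18 ± 0.998 to 1.22 ± 0.563 CPM (-1.38, SE 0.28), with 0.619 in edgeR and 0.0374 in DESeq2. Also higher in myriocin libraries were Dmp1, a matrix protein of bone (0.82, SE 0.19), and the kinase Tnik (0.34, SE 0.09). On the low side were Tmem136 (-0.50, SE 0.10), Igfbp6, which binds insulin-like growth factors (-0.42, SE 0.09), the non-muscle myosin heavy chain Myh14 (-0.29, SE 0.07) and the chaperone Hsph1 (-0.32, SE 0.08).

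The groups did not part on the main axes of variation. The first component of the log2 CPM values held 21.4% of the variance and the second 20.1%, and neither separated the groups (2-sided exact permutation test, p = 0.383 and 0.877). DMSO replicate 2, DMSO replicate 5 and Myriocin replicate 4 lay farthest out. DMSO replicates 4 and 5 and Myriocin replicate 4 carried transcripts of the liver protein albumin (Alb) at 85.6, 63.9 and 73.8 CPM, against 4.44 to 20.6 CPM in the other 8 libraries. The neutrophil gene S100a8 reached 150 CPM in DMSO replicate 2 and 0.0432 to 20.01 CPM elsewhere. Alb was chosen after its values had been seen. Leaving out the 3 libraries with liver transcripts, or the 3 farthest out, left the number of genes past the threshold at 0, while the number at an unadjusted p under 0.05 went from 660 to 1022 and 1140. These alternatives were chosen after seeing the data.

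**Figure D1:**
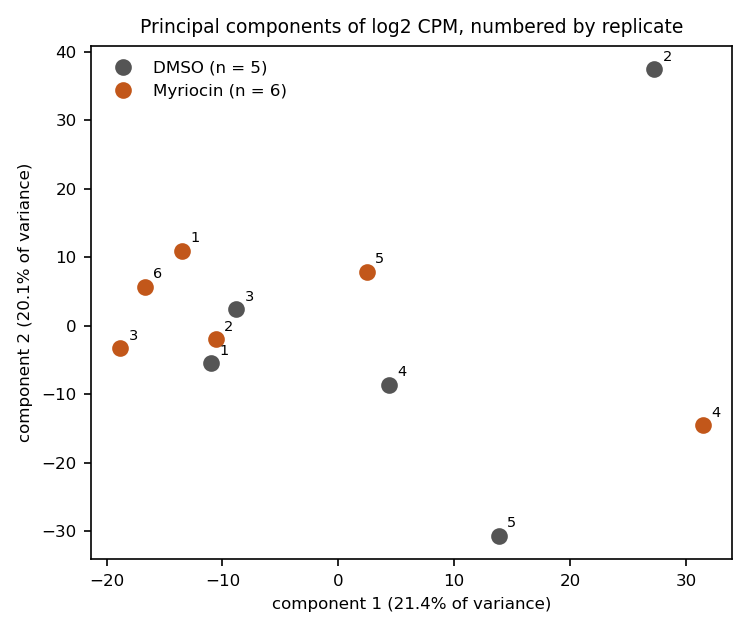
Each dot is 1 library, numbered by replicate, placed by its values on the first 2 principal components of log2 CPM over the tested genes. DMSO libraries are grey and myriocin libraries orange, and the groups overlap, with DMSO replicate 2 at 27.3 and 37.5 and Myriocin replicate 4 at 31.5 and -14.5.

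Genes of fatty acid uptake and oxidation were lower with myriocin. Of 31 tested members, 30 had negative log2 fold changes, with a median of -0.16 and a range from -0.68 to 0.01. The mean log2 CPM of the list was 6.63 ± 0.11 (SD, n = 5) with DMSO and 6.37 ± 0.17 (SD, n = 6) with myriocin. All 6 myriocin libraries lay below the DMSO mean, while single libraries of the groups overlapped. Myriocin replicates 1 and 6, at 6.61 and 6.54, lay above DMSO replicates 2 and 4, at 6.53 and 6.50. Among the members with the smallest p were Mlycd, malonyl-CoA decarboxylase, which removes an inhibitor of fatty acid import into mitochondria (131.5 ± 13.2 against 106.4 ± 9.54 CPM; log2 fold change -0.31, SE 0.08), and Lpl, lipoprotein lipase, which frees fatty acids from circulating triglycerides (464.5 ± 61.8 against 309.3 ± 86.6 CPM; -0.59, SE 0.18). There were 8 members with an unadjusted p under 0.05, all lower, and 0 passed over all genes or adjusted over the list alone. Camera with a preset correlation of 0.01 gave an adjusted p of 1.58e-10 (limma). The call was lost with an estimated correlation, adjusted p = 0.561 with an estimated correlation, and the exact permutation test of the list mean gave p = 0.0216 (2-sided, n = 5 and 6), 0.226 after adjustment over 38 lists.

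Endothelial markers were also lower with myriocin. All 15 tested markers had negative log2 fold changes, with a median of -0.14, and the list mean was 4.66 ± 0.03 (SD, n = 5) with DMSO and 4.51 ± 0.11 (SD, n = 6) with myriocin, lower in 6 of 6 myriocin libraries. Myriocin replicate 3 had the lowest value, 4.29, and without it the median was -0.083 and the adjusted p 0.0224. Cldn5, a protein of endothelial tight junctions, had 21.1 ± 5.33 and 14.8 ± 1.76 CPM (log2 fold change -0.51, SE 0.14); it passed adjusted over the list alone (limited to 15 genes, adjusted p = 0.0395 in edgeR) and not over all genes (0.936). The adhesion molecule Pecam1 (-0.16, SE 0.08) and the receptor Tie1 (-0.15, SE 0.09) did not pass. The adjusted camera p was 0.00114, the adjusted p = 0.561 with an estimated correlation, and the exact permutation p was 0.00649 (2-sided), 0.226 after adjustment.

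Heat shock and protein folding genes were also lower, 19 of 23 members being negative, with a median of -0.10 and 6 at an unadjusted p under 0.05. Hsph1, a chaperone, stood at 113.4 ± 3.28 and 91.0 ± 10.7 CPM and was the only member to pass adjusted over the list alone (adjusted p = 0.0221 in edgeR), with 0.936 over all genes. The small heat shock protein Cryab (-0.27, SE 0.11) and the co-chaperone Bag3 (-0.23, SE 0.09) did not pass. The adjusted camera p was 0.00114, and the adjusted p = 0.561 with an estimated correlation. The exact permutation p of the list mean was 0.0433 (2-sided), 0.329 adjusted. The list mean lay below the DMSO mean in 5 of 6 myriocin libraries.

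The autophagy and lysosome list had 24 of 30 members negative, with a median of -0.055. Its mean lay below the DMSO mean in 6 of 6 myriocin libraries, while single libraries of the groups overlapped. Its leading members were Gabarapl1 (-0.41, SE 0.12) and Map1lc3b (-0.14, SE 0.06), both proteins of the autophagosome membrane, followed by Atp6v0d1, a subunit of the lysosomal proton pump (-0.10, SE 0.06), and 0 members passed either adjustment. The adjusted camera p was 0.0268, the adjusted p = 0.613 with an estimated correlation, and the exact permutation p 0.0195 (2-sided), 0.226 adjusted. The call ended without DMSO replicate 3 (adjusted p = 0.0991), DMSO replicate 4 (0.0529) or Myriocin replicate 5 (0.219). It also ended without the filter on low counts (0.0848), with the replicate number as a block (0.0703) and without the 3 libraries with liver transcripts (0.0911). The median was -0.037 without Myriocin replicate 5 and lay from -0.059 to -0.046 in the other settings named.

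Antioxidant and NRF2 target genes had 19 of 23 members negative, among them the glutathione peroxidase Gpx3 (-0.49, SE 0.17), catalase, Cat (-0.29, SE 0.12), and the regulator Nfe2l2 (-0.13, SE 0.08), with 0 past either adjustment. That list was close to the threshold (adjusted camera p 0.0495, adjusted p = 0.648 with an estimated correlation), with a median of -0.051. Its mean lay below the DMSO mean in 6 of 6 myriocin libraries (exact permutation p = 0.0801, 2-sided), while single libraries of the groups overlapped. It lost its call without DMSO replicate 2, 3 or 5 (adjusted p 0.0854, 0.173 and 0.141) or Myriocin replicate 2, 3, 5 or 6 (0.0528, 0.136, 0.102 and 0.0667), and also without the filter on low counts (0.11), without the most abundant genes (0.0556), with the replicate block (0.0703) and without the 3 libraries farthest out (0.181). The median was -0.032 without DMSO replicate 5, -0.101 without DMSO replicate 1 and -0.089 without Myriocin replicate 4, the call holding in the last pair. It was -0.054 and -0.063 without DMSO replicate 2 or 3. Without Myriocin replicate 2, 3, 5 or 6 it was -0.052, -0.042, -0.053 and -0.046.

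Cytosolic ribosomal protein genes were lower by a small and even amount, 73 of 74 members being negative with a median of -0.095, and 0 reached an unadjusted p under 0.05 or passed either adjustment. Rpl26 (-0.17, SE 0.12), Rpl27 (-0.14, SE 0.10) and Rpl3 (-0.20, SE 0.14) had the smallest p. These genes have many processed pseudogenes, and reads that match several places were set aside by the authors' counting, so the levels are uncertain. The adjusted camera p was 0.00114, with an adjusted p = 0.967 with an estimated correlation, and the exact permutation p was 0.545 (2-sided). The list mean lay below the DMSO mean in 5 of 6 myriocin libraries, but DMSO replicate 1, at 6.84, lay below each myriocin library. The value rested on DMSO replicate 2: without it the median was -0.003 and the adjusted p 0.777, while it was -0.154 without DMSO replicate 1 and -0.159 without Myriocin replicate 4. The call was also lost without DMSO replicate 5 (median -0.042, adjusted p 0.456) or Myriocin replicate 6 (0.127), with the replicate block (0.149) and with a surrogate variable (0.0864). Without the 3 libraries farthest out the list was higher with myriocin, with a median of 0.041 and an adjusted p of 0.00743.

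Genes of the circadian clock and its output were higher, 15 of 20 members being positive with a median of 0.18. The list mean was 5.26 ± 0.12 (SD, n = 5) with DMSO and 5.41 ± 0.08 (SD, n = 6) with myriocin. In 6 of 6 myriocin libraries it lay above the DMSO mean, while single libraries of the groups overlapped. Its leading members were the output factor Tef (0.18, SE 0.07), the repressor Bhlhe41 (0.27, SE 0.12) and Clock itself (0.18, SE 0.08), and 0 passed either adjustment. The adjusted camera p was 5.29e-04, the adjusted p = 0.532 with an estimated correlation, and the exact permutation p was 0.0238 (2-sided), 0.226 adjusted. The call was lost without the 3 libraries with liver transcripts (median 0.12, adjusted p = 0.108) and without the 3 libraries farthest out on the components (0.11, adjusted p = 0.327).

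Contractile genes of fast fibres had 12 of 17 members positive, with a median of 0.14 and a mean of 0.07, and glycolysis and glycogen genes 18 of 24, with a median of 0.10 and a mean of 0.06. The member farthest from 0 in each list was negative, the myosin heavy chain Myh2 at -0.56 and the lactate dehydrogenase subunit Ldhb at -0.51, named after their values were seen. The fast myosin heavy chain Myh4 was the leading member, at 61910 ± 5810 CPM with DMSO (SD, n = 5) and 71200 ± 3151 CPM with myriocin (SD, n = 6; log2 fold change 0.20, SE 0.08), followed by the light chain Myl1 (0.24, SE 0.11) and the calcium store protein Casq1 (0.24, SE 0.11). In the glycolysis list the phosphorylase kinase subunit Phka1 (0.20, SE 0.10) and Gapdh (0.20, SE 0.10) were among the members with the smallest p, and 0 members of either list passed either adjustment. The adjusted camera p was 0.00159 for fast fibres, with an adjusted p = 0.602 with an estimated correlation, and 0.00384 for glycolysis, with an adjusted p = 0.648 with an estimated correlation. The list means lay above the DMSO mean in 5 and 4 of 6 myriocin libraries (exact permutation p = 0.294 and 0.305, 2-sided). Gapdh has many pseudogenes that share its reads. Without Myriocin replicate 4 both calls were lost (adjusted p 0.0664 and 0.155), with medians of 0.114 for fast fibres and 0.069 for glycolysis. That of glycolysis was also lost without DMSO replicate 2 (median 0.068, adjusted p 0.0994) and without the 3 libraries farthest out (median 0.053, adjusted p 0.28). With mitochondrial genes and the 20 most abundant genes left out, the median of the remaining fast fibre members was -0.03 and the adjusted p 0.796, and that of glycolysis 0.0556.

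In total camera called 9 of the 38 lists, 3 higher and 6 lower. With an estimated correlation it called 0 (1 at an unadjusted p under 0.05), fry 0 (5) and the exact permutation test 0 (5), while cameraPR called 11. Leaving out DMSO replicate 5 gave 14 lists and leaving out Myriocin replicate 1 gave 15. Of other random splits of the same libraries into 5 and 6, the median one called 10 lists and the range was 3 to 20, so the number of lists called in the real comparison was not above that of arbitrary splits.

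**Figure D2:**
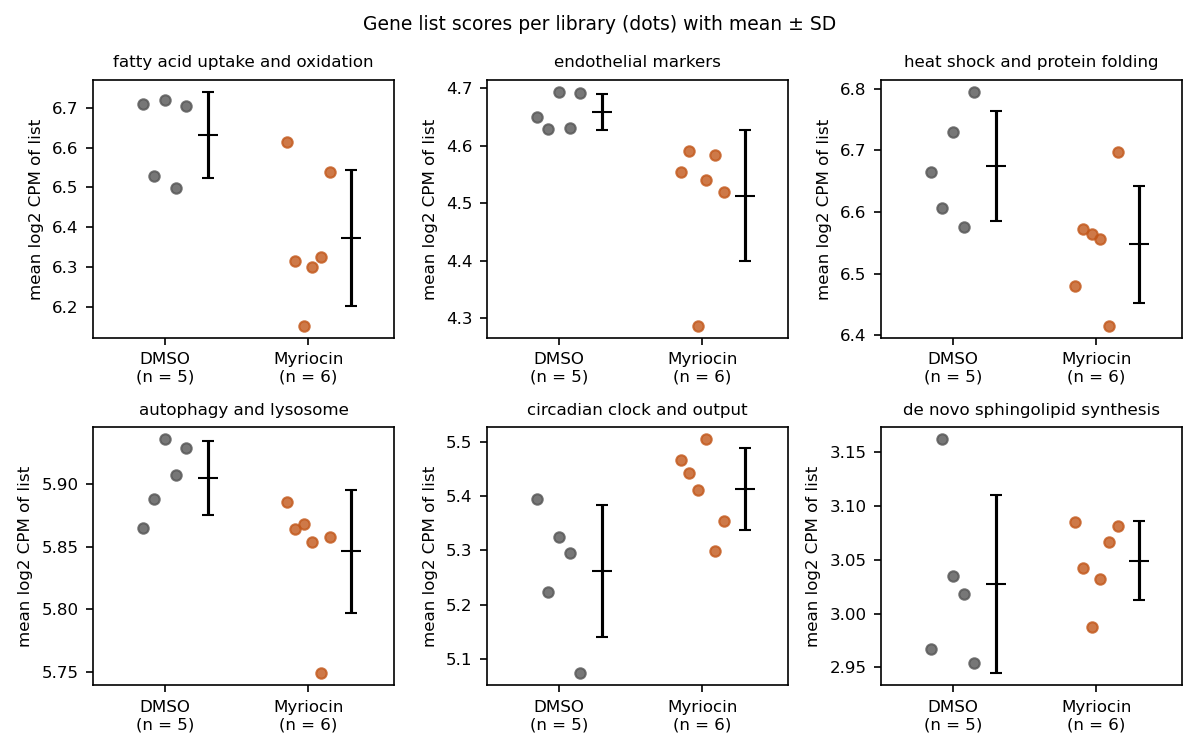
Each dot is the mean log2 CPM of the tested members of a gene list in 1 library, for 6 lists, with DMSO in grey and myriocin in orange; the bars show mean ± SD, and each panel has its own vertical scale. Fatty acid, endothelial, autophagy and heat shock scores were lower with myriocin on average and the clock score higher, while the sphingolipid synthesis score was 3.03 with DMSO and 3.05 with myriocin.

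The other 29 lists did not pass in camera over all 11 libraries, with adjusted p-values of 0.0678 or more, and 13 of them were called under at least 1 alternative. Nuclear-encoded oxidative phosphorylation genes had 68 of 74 members negative with a median of -0.07 (adjusted p 0.0678, 0 members past either adjustment), against a median of -0.03 for 13 mitochondrially encoded genes. CameraPR called the oxidative phosphorylation list lower (adjusted p 0.0144), as did camera without scaling (0.0175), without DMSO replicate 1, 2 or 4 (0.0104, 0.00634 and 2.43e-05), without Myriocin replicate 1, 4 or 5 (0.0396, 1.73e-04 and 0.0183) and without the 3 libraries with liver transcripts (0.035). Without DMSO replicate 5 the same list was called higher, with a median of 0.035 (adjusted p 0.00607). Slow fibre genes had 12 of 16 negative, led by Actn2 (-0.35, SE 0.13) and Myh7b (-0.52, SE 0.21), and an adjusted p of 0.190, and were called lower without DMSO replicate 4 (0.00733), without Myriocin replicate 5 (0.0362) and without the 3 libraries with liver transcripts (5.88e-04). Muscle stem cell and myogenic genes had 18 of 27 positive, and the stem cell regulator Pax7 stood at 1.52 ± 0.565 and 2.51 ± 0.588 CPM (0.72, SE 0.24; adjusted p in edgeR 0.936), with the adhesion protein Jam2 at -0.16 (SE 0.08). That list was called higher without DMSO replicate 5 (0.0406) and without the libraries with liver transcripts (0.00547). In the neuromuscular junction and denervation list 14 of 20 were positive, led by Chrne, the adult acetylcholine receptor subunit (0.38, SE 0.12), and Ache, acetylcholinesterase (0.29, SE 0.09), with an adjusted camera p of 0.190. Atrophy and FoxO target genes split evenly, 13 positive and 12 negative, with Mstn, myostatin, at 0.21 (SE 0.09) and Mt2 at 1.18 (SE 0.57). Extracellular matrix genes were 19 positive and 18 negative, with Thbs1 at -0.63 (SE 0.27) and Lum at 0.30 (SE 0.14).

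Markers of other cell types beyond the endothelium did not pass as lists in camera over all 11 libraries. The fibro-adipogenic progenitor markers had 10 of 14 negative (adjusted camera p 0.121). At an unadjusted p under 0.05 in edgeR 3 of them were lower and 2 higher. Clec3b, at 29.4 ± 3.33 and 23.7 ± 1.92 CPM (-0.31, SE 0.08), passed adjusted over the list alone (adjusted p = 0.0324 in edgeR) and not over all genes (0.936). Ly6a stood at -0.38 (SE 0.13). Neutrophil and mast cell markers were 3 positive and 3 negative, S100a8 and S100a9 having fold changes of -2.35 (SE 1.69) and -2.41 (SE 1.74) that came from DMSO replicate 2 and turned to 1.64 and 1.57 without it. Adipocyte markers had 12 of 13 negative with an adjusted p of 0.342, and Schwann cell markers 9 of 11 with 0.0978. The adipocyte list was called lower by cameraPR (0.0144), without DMSO replicate 5 (0.0406) and without the libraries with liver transcripts (5.33e-04), and higher without DMSO replicate 2 (median 0.321, adjusted p 0.0484). The Schwann cell list was called lower without DMSO replicate 5 (0.0166), Myriocin replicate 2 (0.0433), Myriocin replicate 4 (0.0471) or Myriocin replicate 5 (0.00543) and without either set of 3 libraries (0.00268 and 0.00743). Macrophage, lymphocyte, smooth muscle, tendon and red blood cell markers had adjusted p-values of 0.579, 0.409, 0.275, 0.234 and 0.835. Mitochondrial biogenesis, cholesterol synthesis, and unfolded protein and integrated stress response genes each gave 0.913, triglyceride and fatty acid synthesis and cell cycle genes 0.831, proteasome genes 0.303, and IGF1, insulin and mTOR signalling genes 0.409. For the last of these, and for sphingolipid turnover, mitochondrially encoded, stress response, cholesterol, interferon, cell cycle and neutrophil genes, camera's direction was upward while the median was negative. The difference of list means had the opposite sign to the median for triglyceride synthesis, red blood cell, extracellular matrix, mitochondrially encoded, interferon, cell cycle, cholesterol and IGF1 genes. Immediate early genes, a sign of handling that entered no list test, had a median of -0.13 (exact permutation, p = 0.405, 2-sided). Inflammatory cytokines, type I interferon and MHC genes gave 0.162, 0.913 and 0.190, and senescence and p53 target genes 0.118. Without Myriocin replicate 1 the progenitor (0.0139), macrophage (0.0139), senescence (0.0244), MHC (0.0274) and cytokine (0.0428) lists were called lower, and without DMSO replicate 5 the progenitor (0.0406), MHC (0.0406) and cytokine (0.00484) lists. The MHC and cytokine lists were also called lower without Myriocin replicate 6 (0.018 and 0.0307) and with the replicate block (0.00201 and 0.00947), and the cytokine list without the libraries with liver transcripts (0.0249). Tendon markers were called lower without DMSO replicate 3 (0.034) and proteasome genes without DMSO replicate 1 (0.013), and cell cycle genes higher without DMSO replicate 2 (0.0121) and without the 3 libraries farthest out (0.0103).

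**Figure D3:**
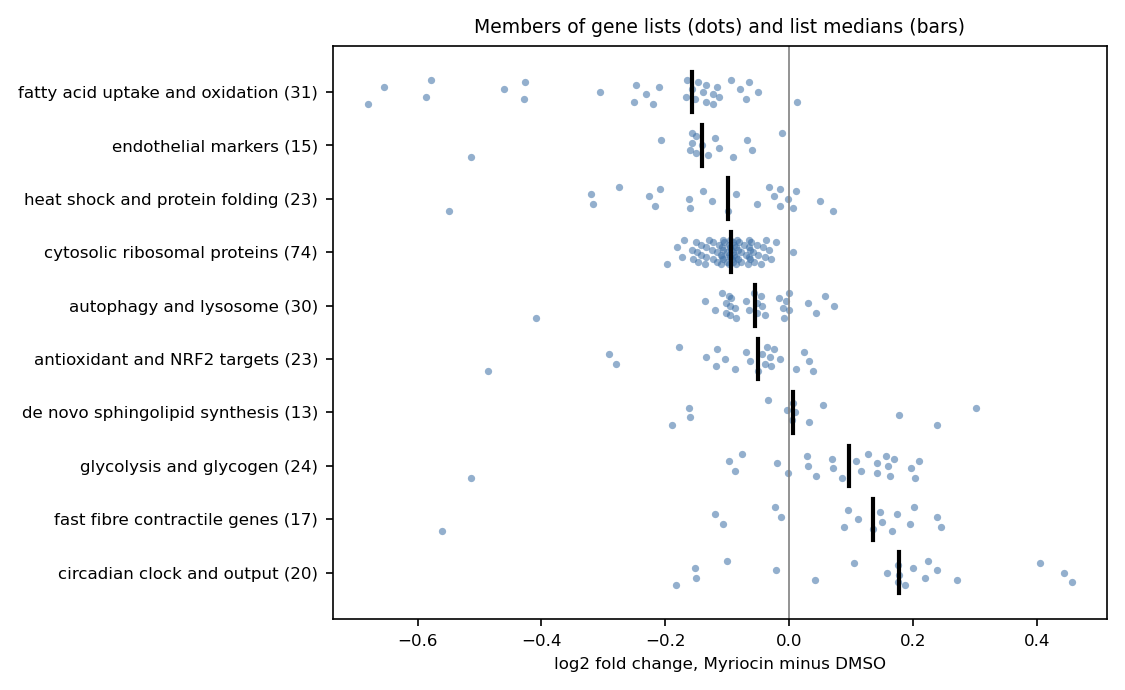
Each dot is the log2 fold change (myriocin minus DMSO) of 1 tested member of a list and each black bar the list's median, for the 9 lists called by camera and the sphingolipid synthesis list, with the number of members in brackets. The fatty acid list runs from -0.68 to 0.01, and the clock list from -0.18 to 0.46.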

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

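Values far from the rest of their group were sought with Dixon's ratio in 194 sets (53 named genes, 39 lists and 5 measures of depth, each in both groups). The genes among these depend on the choice of described lists, made after values were seen. It marked 8, where chance gives 9.7. DMSO replicate 2 stood apart in 3 of them. Its adipocyte score was 5.34 against 2.93 to 3.53 in the other DMSO libraries, its macrophage score was 3.97 against 3.08 to 3.33, and Rpl3 had 91.6 CPM against 53.5 to 57.0 CPM. Myriocin replicate 3 had the lowest endothelial score (4.29 against 4.52 to 4.59) and the lowest tendon score (2.04 against 3.12 to 3.73). Myriocin replicate 5 had the lowest autophagy and lysosome score, 5.75 against 5.85 to 5.89. Myriocin replicate 4 gave 37.4% of its counts to its 20 most abundant genes, against 36.2% to 36.5%. DMSO replicate 4 had 355.3 CPM of Lpl against 482.1 to 502.5 CPM in the other DMSO libraries.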

How the results depend on the processing

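All alternatives but the removal of sets of 3 libraries were planned. The count of genes changed, 0, became 1 with a surrogate variable (Sh3rf2) and 3 with DESeq2 (Sh3rf2, Tirap and Xlr3b), and was 0 under every other alternative run, from 0 to 0 when each library was left out in turn. The count of lists called, 9, became 0 with an estimated correlation, 0 with fry and 0 with the permutation of list means. It ran from 8 to 15 when each library was left out in turn and from 6 to 13 under the others. The run with an estimated correlation differed from the main one only in the correlation assumed within lists. The cause of the other changes was not tested. For the 9 lists singly, 176 values kept direction and call, 56 lost the call and in 2 camera's direction turned, both for the ribosomal list, its median being -0.003 without DMSO replicate 2. For the named genes 1449 stayed, 4 passed and 24 turned.

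The correlations of same-numbered libraries, after removal of group means, were -0.003, -0.132, 0.075, 0.087 and -0.101. They gave no sign of pairing by replicate number but cannot exclude it. With the replicate block over 10 libraries the counts were 0 genes and 8 lists, 6 of them among the 9.

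Some values turned sign, the cause not being tested. Sptlc1 was -0.032 without scaling, -0.018 with sample weights, -0.057 without the 3 libraries far out on the components and -0.038 to 0.069 with each library left out. Sptlc2 was -0.034 without scaling, -0.162 without the 3 libraries with liver transcripts and -0.118 to 0.159 with each library left out. Without the 3 libraries far out on the components the median of the ribosomal list was 0.041 (adjusted p = 0.00743), Rpl26 0.012, Rpl27 0.031, S100a8 0.816 and S100a9 0.751. S100a8 and S100a9 were 0.176 and 0.311 with the replicate block, 0.77 and 0.628 with a surrogate variable, and -3.309 to 1.642 and -3.343 to 1.566 with each library left out. Without mitochondrial genes and the 20 most abundant genes the fast fibre median was -0.025. The ribosomal median ran from -0.159 to -0.003 with each library left out. Leaving out 1 library moved 14 of the 53 named genes by over 1.5 times: besides Sptlc1, Sptlc2, S100a8 and S100a9, without DMSO replicate 2 Cers1 (0.147), Rpl3 (-0.02), Rpl26 (-0.08) and Rpl27 (-0.063), without DMSO replicate 5 Mstn (0.139), Rpl26 (-0.092) and Rpl27 (-0.074), without DMSO replicate 3 Nfe2l2 (-0.075), without Myriocin replicate 1 Lum (0.182), and without Myriocin replicate 3 Mt2 (0.663), Pecam1 (-0.106) and Tie1 (-0.083). None of these genes was called in edgeR. Depth was alike in all libraries, and genes near the floor, such as Mt2, carry wide errors.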

Other observations

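The libraries differed in transcripts that followed neither treatment, given here as values chosen after they were seen. The slow myosin Myh7 ranged from 1.08 CPM in DMSO replicate 4 to 145 CPM in Myriocin replicate 5, and was 118 and 98.0 CPM in DMSO replicates 2 and 3 and 1.88 CPM in Myriocin replicate 3. The slow troponin Tnnt1 had 79.8 and 74.5 CPM in Myriocin replicate 5 and DMSO replicate 2 and 2.84 CPM in Myriocin replicate 3. The developmental myosins Myh3 and Myh8, made in growing or regenerating fibres, had 29.1 and 58.7 CPM in DMSO replicate 5, 36.1 and 69.8 CPM in Myriocin replicate 1, and 19.6 and 27.1 CPM in Myriocin replicate 6, while Myh8 was 4.26 to 10.9 CPM in the others. Mymk, which fuses myoblasts, was 5.71, 6.17 and 3.20 CPM in those 3 libraries and 0.132 to 1.52 CPM in the others. DMSO replicate 2 had 932 CPM of Fasn, 34.9 CPM of Cidea and 244 CPM of S100a9, where the next highest libraries had 466.7, 5.23 and 30.9 CPM.

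The tests of oxidative phosphorylation, endothelial share, peroxisomal genes, liver genes and clock phases, and the splits for single lists, were chosen after the patterns they address had been seen; the splits for the counts of genes and lists were planned. The rule for reading a test was set before its value was seen for the liver, peroxisomal, endothelial and split tests, and after for oxidative phosphorylation and the clock phases. By the rule set for splits, the share for the clock list counted against chance. So did that for the fatty acid list if the real split was left out of the count. Both are read here as open, since each list was picked after its value was seen. The rule for oxidative phosphorylation and endothelial share was then made stricter after their values were seen: by the rule first set, both values would have counted for the explanation, and they are read here as open because their intervals hold both 0 and the size of the difference. In 100 splits of the 11 libraries into 5 and 6, the real one included, 100 gave at least the 0 genes of the real comparison, the highest of the others giving 79; with a real count of 0 this holds for any split and decides nothing. The split with 79 genes set DMSO replicates 1, 2, 4 and 5 with Myriocin replicate 4 against the rest. It differs from the real grouping by the exchange of DMSO replicate 3 and Myriocin replicate 4. It kept together DMSO replicates 2 and 5 and Myriocin replicate 4, the libraries farthest out on the components. So did splits with 2311, 2280, 2215 and 2093 genes at an unadjusted p under 0.05, against 660 in the real comparison. Others that did so gave fewer, such as 753 and 555. The split was picked as the highest, so its count cannot be weighed against chance, and its cause was not tested. For lists, 70 of the 100 splits called as many as the 9 of the real comparison, the highest of the others calling 20, and chance cannot be excluded for the number of lists called.

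Whether the lower fatty acid list reflects the treatment stays open. Of the 100 splits, 5, the real one included, gave a camera p as small as the real 4.16e-12, the smallest of the others being 6.11e-18. The list had the smallest camera p of the 38 lists tested. In 62 of the 100 splits, the real one included, some list had a camera p as small, so chance is not excluded. A second list of 21 peroxisomal oxidation and PPAR target genes not looked at before was lower too. Its mean was 5.08 ± 0.08 against 4.96 ± 0.08 (exact permutation, unadjusted p = 0.00649), with 17 of 21 members negative. In edgeR 5 members were lower and 0 higher at an unadjusted p under 0.05. The lower values may thus extend beyond the fatty acid list, a hypothesis found and tested on the same libraries. Random splits were not run for the second list, and a role of PPAR receptors was not tested. A lower content of mitochondria or oxidative fibres is not excluded. The change of the fatty acid list minus that of oxidative phosphorylation genes was -0.21, with a 95% interval from -0.47 to 0.06 (exact permutation, p = 0.106). The direction of the oxidative phosphorylation list turned without DMSO replicate 5. With the endothelial score as covariate 48.5% of the difference stayed (-0.12, interval from -0.37 to 0.12), which spans 0 and the undivided -0.26, so a lower share of endothelial cells cannot be told apart with 11 libraries.

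RNA from liver tissue may account for the albumin and other hepatocyte transcripts of DMSO replicates 4 and 5 and Myriocin replicate 4. Of 28 further hepatocyte genes not looked at before, 75% (21) had these libraries as their 3 highest, a share at the bound set for it. Chance gives 0.606% for a single gene. The share cannot be weighed against that, since the libraries were picked for their hepatocyte transcripts and such genes may vary together. The mean of the 28 genes was 4.22, 3.14 and 4.87 CPM in the 3 libraries. It was 8.81 CPM in DMSO replicate 2 and 1.885 to 2.942 CPM in the others. Apoa1 was 11.3, 12.5 and 16.6 CPM in the 3 libraries and 0.349 to 2.998 CPM in the others, and 4 of the 28 genes exceeded 1 CPM in all of the other 8 libraries, Cyp2e1 among them, highest in DMSO replicate 2 at 212 CPM. Transfer during dissection and index exchange in sequencing were not tested, and no biological explanation was tested.

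The circadian list was higher with myriocin, and 4 of the 100 splits, the real one included, gave a camera p as small as the real 2.79e-05 (smallest of the others 4.95e-07). As the list was picked from 38 after its value was seen, and had an adjusted permutation p of 0.226 and an adjusted p = 0.532 with an estimated correlation, chance is not excluded for it either. A different time of day of sampling may be a cause and stays open. Genes that peak with Dbp and the Per genes were 5.50 ± 0.23 with DMSO and 5.76 ± 0.18 with myriocin, and those that peak with Arntl 3.89 ± 0.31 and 3.87 ± 0.22. The difference of the 2 scores changed by -0.28, with a 95% interval from -0.86 to 0.31 (exact permutation, p = 0.314), too wide to decide. The call did not hold without the 3 libraries with liver transcripts (median 0.118).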
